A study of Mus musculus with 11 samples.

How the data were processed

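Pancreatic islets were isolated from male C57BL/6 mice, and 11 RNA-seq libraries were made from them with an RNeasy Micro extraction and a TruSeq stranded mRNA kit, per the labels' protocols. The labels give the tissue as pancreas and the cell type as beta cells, while the design text speaks of isolated islets. The groups were vehicle on chow (control, n = 3), vehicle on a 60% high fat diet (HFD, n = 4) and the same diet with momelotinib at 12.5 mg/kg per day (HFD_MOM, n = 4). Treatment began after 2 weeks of diet and lasted 4 weeks. The design text gives the age of the mice as 8 weeks or 6 to 9 months and does not tie an age to a library. Nothing states that each library came from a different mouse, so p-values measure the spread between these samples, which may be technical. Replicate numbers were given in accession order and pair nothing.

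Per the submitters' processing notes, reads were handled with fastp and kallisto on genome build GRCm39. The versions, the annotation release and the way transcripts were summed to genes are not given in the sources used here. The deposited table holds estimated counts per Ensembl gene, as the authors made them, without normalisation. It has 52178 gene IDs, and 48845 of them were paired with a symbol from GENCODE M21 and RefSeq names. The 3333 IDs without a symbol held 0.241% to 0.761% of the counts of a library. The reference used for names is of the older build GRCm38, so no coordinates are given. Estimated counts were rounded to whole numbers before testing. Kallisto shares reads between near-identical copies, so single members of the amylase, trypsin, histocompatibility and immunoglobulin families are uncertain. Library totals ranged from 16447053 to 22890327. Replicates of a group differed by far more than sampling noise (chi-square per gene 12.5 to 270.4 over 15 pairs), so each library was counted once.

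Genes were kept with edgeR's filterByExpr, normalised with TMM factors and tested with the quasi-likelihood F-test of edgeR 4.0.16 (robust fit, two-sided) in R 4.3.3, with all 11 libraries in 1 fit. Benjamini-Hochberg adjustment covered the 15761 tested genes, with a threshold of 0.05. The standard error (SE) is the absolute log2 fold change divided by the square root of F. CPM are TMM-normalised, and log2 CPM use a prior count of 2. On simulated counts with 15761 genes, the procedure recovered 20.9%, 55.2% and 78.8% of genes changed by 1.5-fold, 2-fold and 4-fold between HFD and control. It recovered 20.9%, 62.7% and 87.9% between HFD_MOM and HFD, and 19.4%, 74.6% and 74.2% between HFD_MOM and control. In the same order 3.64%, 5.47% and 4.10% of the calls were false, with a shifted ribosomal list counted among the true calls. Genes were drawn independently, without shared differences between libraries such as those in acinar content. These shares may therefore not carry over to the real libraries.

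The tests, the 42 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists held 834 entries and 781 different genes. Of these, 9 were found through a synonym and 1 was not matched (Rigi). They covered beta identity, beta disallowed genes, beta immaturity and compensation, secretory granule and exocytosis, senescence, p53 targets, the senescence-associated secretory phenotype (SASP), interferon stimulated genes, major histocompatibility complex (MHC) class I and class II presentation, JAK-STAT feedback and STAT3/STAT5 targets, JAK-STAT components, BMP-SMAD targets, NF-kB targets, cell cycle, unfolded protein response, ATF4 response, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation with PPAR targets, nuclear OXPHOS, mitochondrially encoded genes, glycolysis, hypoxia, NRF2, immediate early genes, heat shock, ribosomal proteins, and lysosome with autophagy. A further 13 lists held markers of fibroblasts and stellate cells, macrophages, T cells, B and plasma cells, neutrophils, endothelium, acinar, ductal, alpha, delta and PP, and Schwann cells, adipocytes and erythrocytes. The lists overlap. Lists with at least 3 tested genes (41 lists) were tested on log2 CPM with camera from limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, each with Benjamini-Hochberg adjustment over the lists. Marker shares were compared with exact two-sided permutation tests in SciPy, 42 in all. The smallest p these can give is 0.0571 for 3 against 4 libraries and 0.0286 for 4 against 4.

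The rule named, for each comparison and direction, the 8 genes with the smallest p past the threshold, or the 3 with the smallest p where fewer than 3 passed (given as not past it), leaving out predicted and clone names. It added up to 2 members of each list past the threshold or, where none passed, the 2 with the smallest p in the direction of a list past the camera threshold. It always named a fixed set that included Ins1, Ins2, Gcg, Jak1, Jak2, Stat3, Socs3, Cish, Cdkn1a and Cdkn2a. The text names fewer members of a list than the rule allows, smallest p first. Alternatives were other normalisations, filters and thresholds, DESeq2 1.42.0, limma voom with and without quality weights, an acinar marker covariate, fits of only the groups compared, and leaving out each library in turn. Alternatives chosen after seeing the data were a T and B cell marker covariate, an adipocyte marker covariate and leaving out pairs of libraries with intestinal or lymph node transcripts. Intestinal and lymph node transcripts were scored with 2 short marker lists written afterwards. The adipocyte covariate summed its markers, and Fabp4 held most of those counts.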

Results

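Islet RNA from 11 libraries was profiled by stranded mRNA sequencing to compare chow-fed mice, mice on a high fat diet, and mice on the same diet given momelotinib, an inhibitor of the kinases JAK1 and JAK2 that act below interferon and cytokine receptors. The control libraries (n = 3) held 17220000 ± 825600 (SD) estimated counts and the HFD libraries (n = 4) 17850000 ± 1912000. The HFD_MOM libraries (n = 4) held 21880000 ± 699100, and each of them was deeper than every other library. The labels name no sequencing batch, and one that set these libraries apart would go with momelotinib in both of its comparisons. Between 20386 and 22092 genes had a count in a library.

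Transcripts of acinar cells, which make digestive enzymes, took a large part of every library. The acinar markers made up 30.2% ± 7.54 (SD, n = 3) of counts in control, 32.1% ± 8.25 (n = 4) in HFD and 36.1% ± 8.95 (n = 4) in HFD_MOM. Ins1 and Ins2, the insulin genes of beta cells, made up 10.3% ± 3.24, 8.80% ± 3.32 and 7.50% ± 3.14 in the same order. None of these differences exceeded the spread between libraries (exact permutation tests, p = 0.343 to 0.80 before adjustment). With every copy of Amy2a counted, among which reads are shared, the acinar share was 44.3%, 45.9% and 51.7%, and 30.9% to 62.2% over the libraries. B and plasma cell markers took 0.258% ± 0.0424 in control, 0.560% ± 0.203 in HFD and 0.50% ± 0.105 in HFD_MOM. Both diet groups lay above all control libraries in this share, at the smallest p that 3 against 4 allows (exact permutation p = 0.0571, Benjamini-Hochberg 0.60). The HFD libraries did so at the same p for T cell markers (0.00818% ± 0.00427 against 0.00213% ± 0.000966) and adipocyte markers (0.00124% ± 4.87e-05 against 0.000787% ± 0.000262). Most adipocyte marker counts were Fabp4. In HFD 1 Cidec added 55 counts, against at most 9 in a control library, and the place of HFD 1 above all controls leans on it. Cidec was also high in HFD_MOM 4 (67 counts), and both libraries carried intestinal transcripts. No share passed the adjusted threshold in the 42 tests, and this design could not have passed it.

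**Figure D1:**
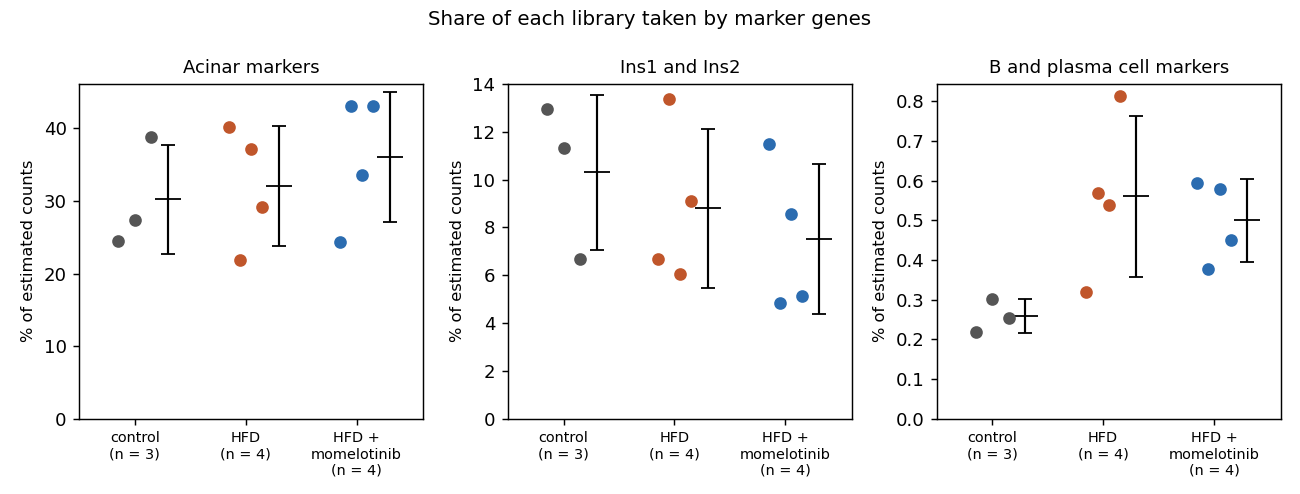
Percent of estimated counts (y axis) taken by acinar markers, by Ins1 with Ins2 and by B and plasma cell markers in each library of the 3 groups (x axis). Points are libraries, and the bar beside them is the mean ± SD. Acinar markers ranged from 21.8% to 43.1% and overlapped between the groups, while B and plasma cell markers averaged 0.258% in control and 0.560% in HFD.

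What the high fat diet did to islet expression was asked by comparing HFD with control. Plin2, which coats lipid droplets, averaged 23.9 ± 3.05 CPM (SD, n = 4) in HFD and 12.0 ± 2.15 (n = 3) in control, with no overlap between the groups, and its log2 difference of 0.998 (SE 0.13) had the smallest adjusted p among the named genes (edgeR, adjusted p = 0.0595). Cpt1a, which carries fatty acids into mitochondria for oxidation, averaged 45.6 ± 0.918 CPM against 29.5 ± 5.58 (log2 difference 0.63, SE 0.12, edgeR adjusted p = 0.396). These genes belong to the fatty acid oxidation and PPAR target list, which rose as a group: 19 of its 21 tested members were higher, and 7 passed 0.05 when adjusted over the list alone against 0 over all genes (camera from limma, adjusted p = 1.29e-09, and adjusted p = 0.334 with an estimated correlation). Fabp4, the 1 adipocyte marker tested, was higher too, by 0.56 (SE 0.22, edgeR, adjusted p = 0.453). With fry from limma, the same list reached an adjusted p of 0.0866 for a shift in 1 direction and 4.83e-05 for change in either direction. Across all 15761 genes no gene passed the threshold in edgeR, while DESeq2 called 73 (61 higher, 12 lower). In edgeR 1592 genes had an unadjusted p under 0.05 (974 higher, 618 lower), where chance would give 788.1. With 1 library left out this count ran from 674 (without control 1) to 2626 (without HFD 2). It was 651 without HFD 1 and HFD 4, the libraries with lymph node transcripts. The excess over chance thus depended on single libraries.

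Genes of interferon and antigen presentation were higher on the diet. Of 54 interferon stimulated genes, 51 were higher, with a median log2 difference of 0.50, 24 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone. The list rose in camera (limma, adjusted p = 1.6e-13, and adjusted p = 0.334 with an estimated correlation). With the T and B cell marker covariate, chosen after seeing the data, its median was 0.22 and it passed (camera from limma, adjusted p = 1.22e-05, and adjusted p = 0.895 with an estimated correlation), while the MHC class I, NF-kB and JAK-STAT lists below did not. Parp9 differed by 0.44 (SE 0.12) and Oas3, a sensor of double-stranded RNA, by 1.25 (SE 0.37). All 16 MHC class I presentation genes were higher, and 11 passed when adjusted over the list alone (camera from limma, adjusted p = 3.56e-11, and adjusted p = 0.334 with an estimated correlation). Tap2, a peptide transporter of this pathway, differed by 0.56 (SE 0.12) and H2-K1 by 0.61 (SE 0.14). All 22 NF-kB targets were higher, 8 past 0.05 over the list alone, with Tnfaip3 at 0.86 (SE 0.21), and 17 of 18 JAK-STAT feedback and STAT3/STAT5 targets were higher, with Pim1 at 0.75 (SE 0.21) and Socs3 at 0.59 (SE 0.18). Both lists rose in camera (limma, adjusted p = 1.29e-09 and 0.000112, and adjusted p = 0.334 for each with an estimated correlation). Among the JAK-STAT components, 16 of 22 were higher, with Ifngr2 at 0.54 (SE 0.13) and Jak2 at 0.29 (SE 0.09) (camera from limma, adjusted p = 0.00386, and adjusted p = 0.42 with an estimated correlation). Adjusted over the list alone, 5 feedback genes (4 higher, 1 lower) and 2 components (1 higher, 1 lower) passed, against 0 over all genes.

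Markers of immune cells moved with these groups. All 14 T cell markers were higher, with a median log2 difference of 1.95, and all 14 passed when adjusted over the list alone. Cd4 differed by 1.59 (SE 0.42) and Trbc1, a T cell receptor segment, by 2.57 (SE 0.74). Over the alternatives Trbc1 ran from 2.13 to 3.53, the latter without control 3. All 14 B and plasma cell markers were higher, with the antibody light chain Igkc at 1953 ± 417 CPM (SD, n = 4) against 889.5 ± 185 (n = 3). The 6 tested neutrophil markers were all higher, from low levels, with Ltf at 1.14 ± 0.478 CPM (n = 4) against 0.10 ± 0.0869 (n = 3). The 3 lists rose in camera (limma, adjusted p = 1.37e-11, 8.63e-09 and 0.00122, and adjusted p = 0.36 for each with an estimated correlation). Macrophage, endothelial and fibroblast markers also rose (14 of 19, 14 of 17 and 20 of 22 higher; camera from limma, adjusted p = 0.0181, 0.00176 and 0.00033), with Lgals3 at 1.03 (SE 0.25), Pecam1 at 0.65 (SE 0.20) and Pdgfra at 1.12 (SE 0.38). With an estimated correlation their adjusted p were 0.645, 0.476 and 0.511. As shares of all counts none of these 3 differed by more than the spread between libraries, nor did neutrophil markers. Exact permutation p was 0.686 for macrophage, 0.40 for endothelial, 0.171 for fibroblast and 0.229 for neutrophil markers. Itgax, a leukocyte integrin, and Mir142hg, the host gene of a blood cell microRNA, had the next smallest p among the named genes higher on the diet and differed by 0.86 (SE 0.14) and 2.25 (SE 0.38) (edgeR, adjusted p = 0.18 and 0.253). Adjusted over the list alone, 3 B and plasma cell, 4 neutrophil and 1 macrophage marker passed, and 0 endothelial or fibroblast markers. Ccl21a, a gene of lymph node stroma chosen after its values were seen, stood at 95.3 and 51.5 CPM in HFD 1 and HFD 4 against no more than 4.55 in the other libraries. Glycam1 (53.6 and 30.1, no more than 1.87 elsewhere) and Madcam1 (4.76 and 7.83, no more than 1.004) of the same list followed it, and Cxcl13 did not (2.81 and 20.2).

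Beta cell genes were lower on the diet. Of 25 beta identity genes, 22 were lower. Mafa, a transcription factor of mature beta cells, averaged 156 ± 28.3 CPM (SD, n = 4) against 276.7 ± 71.2 (n = 3), a log2 difference of -0.83 (SE 0.19), and was the 1 member past 0.05 over the list alone. Nkx6-1 differed by -0.29 (SE 0.11). Of 26 secretory granule and exocytosis genes, 25 were lower, with the calcium channel gene Cacna1a at -0.30 (SE 0.11). Of 28 unfolded protein response genes, 22 were lower, with the stress sensor Ern1 at -0.29 (SE 0.09). The 3 lists fell in camera (limma, adjusted p = 9.35e-06, 6.03e-07 and 0.0229, and adjusted p = 0.463, 0.463 and 0.64 with an estimated correlation). The beta disallowed list, of genes that mature beta cells normally keep silent, rose, 14 of 15 being higher, with Mgst1 at 0.70 (SE 0.23) (camera from limma, adjusted p = 0.000112, and adjusted p = 0.36 with an estimated correlation). These libraries also held other cell types, and Pdgfra of this list is a fibroblast marker too. Which cells carried the rise was not tested. Ins1 and Ins2 differed by -0.21 (SE 0.29) and -0.22 (SE 0.35), and Gcg, the alpha cell hormone gene, by -0.12 (SE 0.31). Other genes named beforehand did not pass either: Jak1 at 0.08 (SE 0.08), Stat3 at 0.15 (SE 0.11), Cish at 1.01 (SE 0.997; -0.17 without HFD 1) and Cdkn1a at 0.43 (SE 0.28). Cdkn2a had 2 to 8 counts per library and was not tested. With the T and B cell marker covariate, chosen after seeing the data, the medians of the beta identity, secretory granule and beta disallowed lists turned to 0.086, 0.0403 and -0.117, and none passed. The genes with the smallest p lower on the diet were Rab33b at -0.37 (SE 0.07), Ppp4r4 at -0.61 (SE 0.13) and Fhdc1 at -0.51 (SE 0.11) (edgeR, adjusted p = 0.334, 0.396 and 0.396).

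A further 8 lists rose in camera. These were the SASP list (31 of 38 higher; Plaur 1.39, SE 0.34), immediate early genes (21 of 22; Klf2 0.81, SE 0.28), ribosomal proteins (35 of 35; Rps9 0.32, SE 0.15), MHC class II presentation (8 of 8; H2-Oa 1.28, SE 0.50, and 2.02 without control 3), BMP-SMAD targets (9 of 10; Id2 0.60, SE 0.20), cell cycle (31 of 40; Mcm6 0.35, SE 0.15), p53 targets (14 of 21; Trp53inp1 0.37, SE 0.10) and glycolysis (12 of 15; Pfkp 0.34, SE 0.09). Their adjusted p in camera from limma ran from 6.95e-07 to 0.0407, and from 0.36 to 0.64 with an estimated correlation. Over the alternatives H2-Oa ran from 0.944 to 2.02. The lists that did not pass were senescence, ATF4, cholesterol synthesis, fatty acid synthesis, nuclear OXPHOS, mitochondrially encoded, hypoxia, NRF2, heat shock, lysosome and autophagy, beta immaturity, and the acinar, ductal, alpha, delta and PP, Schwann and erythrocyte markers (camera from limma, adjusted p = 0.0799 to 0.874). In 6 of these the median, the mean and the camera direction differed in sign: beta immaturity (median -0.02, mean 0.43, camera down), ATF4 (-0.02, 0.02, up), heat shock (-0.02, 0.04, down), ductal (0.03, 0.17, down), alpha (-0.06, 0.02, down) and delta and PP markers (0.06, 0.02, down). Adjusted over the list alone, 3 SASP genes (2 higher, 1 lower), 1 p53 target and 1 glycolysis gene passed, and in lists that did not pass 1 hypoxia gene (higher) and 2 lysosome and autophagy genes (1 higher, 1 lower), against 0 over all genes. Adipocyte markers had 1 tested member and were not tested as a list. With the T and B cell marker covariate 10 lists passed in place of 24, 4 of them shared in the same direction, and ribosomal proteins fell (median -0.14, camera from limma, adjusted p = 0.00151, and adjusted p = 0.895 with an estimated correlation). With this covariate and an estimated correlation 0 lists passed. With the adipocyte markers as a covariate, chosen after seeing the data, the interferon median was 0.23, endothelial markers turned (median -0.00839) and the p53, BMP-SMAD, glycolysis and macrophage lists did not pass.

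**Figure D2:**
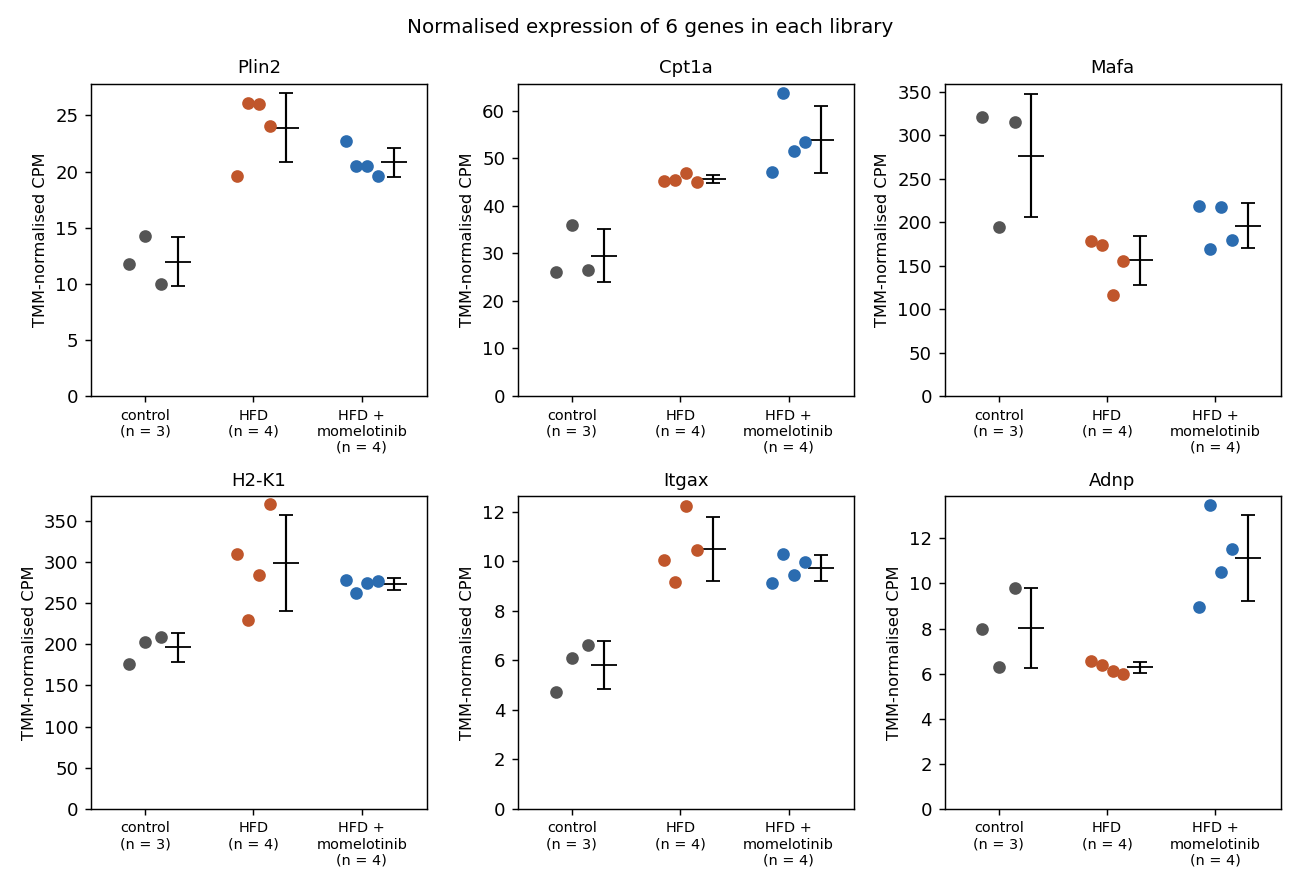
TMM-normalised CPM (y axis, from 0) of 6 genes in each library of the 3 groups (x axis). Points are libraries, and the bar beside them is the mean ± SD. Plin2 averaged 12.0 CPM in control, 23.9 in HFD and 20.8 in HFD_MOM, and Mafa 276.7 in control and 156 in HFD.

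The effect of momelotinib on the diet was asked by comparing HFD_MOM with HFD. Differences were small: the median absolute log2 difference was 0.09 with a median SE of 0.15. Adnp, a chromatin regulator, averaged 11.1 ± 1.90 CPM (SD, n = 4) with momelotinib and 6.27 ± 0.263 (n = 4) without, a log2 difference of 0.82 (SE 0.15). Luc7l3 and Dhdh differed by 0.23 (SE 0.05) and 0.29 (SE 0.07). Mir142hg, Herc2 and Ltf were the lower named genes, at -1.55 (SE 0.33), -0.29 (SE 0.07) and -2.32 (SE 0.60, and from -3.52 without HFD_MOM 1 to -1.98 over the alternatives). None passed (edgeR, adjusted p = 0.9997 for each), and no gene of 15761 did in edgeR, where 353 had an unadjusted p under 0.05 against 788.1 expected by chance. DESeq2 called 2, Gm14440 and Adnp. Gm14440 was chosen after its values were seen, and its DESeq2 log2 estimate of 20.68 stood beside 6.87 (SE 3.57) in edgeR.

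Cholesterol synthesis, interferon and neutrophil lists had the smallest p at the preset correlation among those that fell with momelotinib, and with an estimated correlation neutrophil markers had the smallest (median -2.02, camera from limma, adjusted p = 0.441). Of 25 cholesterol synthesis genes, 22 were lower, with a median of -0.18, and 0 passed when adjusted over the list alone. Srebf2, the regulator of this pathway, averaged 76.2 ± 3.34 CPM (SD, n = 4) against 88.5 ± 1.81 (n = 4), a log2 difference of -0.22 (SE 0.06). Of 54 interferon stimulated genes, 48 were lower, with a median of -0.19, and 0 passed over the list alone. Ifi44 differed by -0.88 (SE 0.38). Both lists fell in camera (limma, adjusted p = 8.06e-08 and 3.21e-06, and adjusted p = 0.691 and 0.826 with an estimated correlation). MHC class I presentation fell as well, with 15 of 16 lower and Tap2 at -0.21 (SE 0.11) (camera from limma, adjusted p = 0.0176, and adjusted p = 0.826 with an estimated correlation). The JAK-STAT feedback list, with 13 of 18 lower and a median of -0.14, did not pass, nor did the JAK-STAT components with 15 of 22 lower (camera from limma, adjusted p = 0.161 and 0.268). Socs3 differed by -0.13 (SE 0.16), Cish by 0.32 (SE 0.88; -0.69 without HFD_MOM 4 and 1.499 without HFD 1), Stat3 by -0.22 (SE 0.10), Jak1 by -0.02 (SE 0.07) and Jak2 by -0.04 (SE 0.08).

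Cell type markers moved in the same comparison. Neutrophil, endothelial, T cell, delta and PP cell and erythrocyte markers fell (6 of 6, 14 of 17, 13 of 14, 6 of 6 and 5 of 5 lower), with Robo4 at -0.39 (SE 0.16), Trbc1 at -1.0 (SE 0.60), the gut hormone gene Pyy at -0.52 (SE 0.16) and Alas2 at -0.71 (SE 0.48). Acinar markers rose in camera, 28 of 31 being higher, with Pnliprp1 at 0.54 (SE 0.45). The adjusted p of these marker lists in camera from limma ran from 3.21e-06 to 0.0333, and from 0.441 to 0.826 with an estimated correlation. As shares of all counts none of them differed by more than the spread between libraries. Exact permutation p was 0.543 for acinar markers and 0.114 to 0.40 for the lists that fell. Heat shock and unfolded protein response genes fell (9 of 12 and 19 of 28 lower), with Hspe1 at -0.24 (SE 0.08) and Hyou1 at -0.28 (SE 0.17). Mitochondrially encoded and ATF4 response genes rose (13 of 13 and 17 of 20 higher), with mt-Nd6 at 0.54 (SE 0.19) and Cebpb at 0.33 (SE 0.23). Without HFD_MOM 4 the ATF4 list did not pass and its camera direction turned (median 0.0263, camera from limma, adjusted p = 0.991). The adjusted p of these lists in camera from limma ran from 0.0029 to 0.0333, and from 0.821 to 0.826 with an estimated correlation. Adjusted over the list alone, 1 neutrophil and 1 delta and PP cell marker passed, and 0 in the other lists that passed camera. Apoa4, an intestinal gene chosen after its values were seen, stood at 446 CPM in HFD 1 and 642 in HFD_MOM 4 and at no more than 35.7 elsewhere. Of the 41 lists, 13 passed at the preset correlation (3 higher, 10 lower), 8 without HFD_MOM 4, and 6 without both libraries that carried intestinal transcripts. Only 5 of these 8, and all of these 6, were among the 13 in the same direction. The interferon, cholesterol synthesis and unfolded protein response lists passed in the same direction in both of these settings. With all libraries and an estimated correlation, 0 of the 41 lists passed. Other splits of the same libraries passed a median of 14 lists at the preset correlation, so 13 is no more than regrouped libraries gave. Without HFD 1 and HFD 4, which carried lymph node transcripts, the MHC class I, T cell and erythrocyte lists changed direction (medians 0.0174, 0.12 and 0.0392). Median, mean and camera direction differed in sign for SASP (-0.04, 0.02, up), nuclear OXPHOS (0.0006, 0.01, down), NRF2 (-0.04, 0.01, down) and immediate early genes (-0.03, -0.01, up), none of which passed. Beta identity genes were not shifted (13 of 25 higher; camera from limma, adjusted p = 0.734), Ins1, Ins2 and Gcg differed by -0.06 (SE 0.27), -0.07 (SE 0.32) and -0.29 (SE 0.29), and Cdkn1a by -0.13 (SE 0.26).

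**Figure D3:**
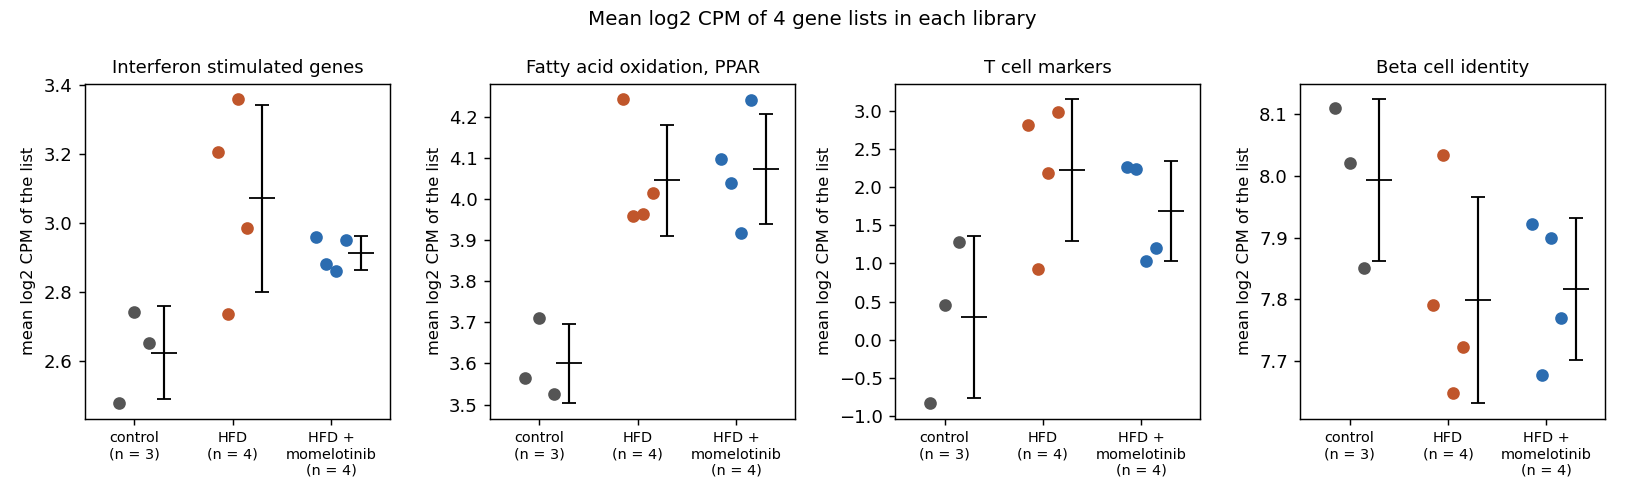
Mean log2 CPM of 4 gene lists (y axis, not starting at 0) in each library of the 3 groups (x axis). Points are libraries, and the bar beside them is the mean ± SD. Interferon stimulated genes averaged 2.63 in control, 3.07 in HFD and 2.91 in HFD_MOM, and fatty acid oxidation genes 3.60, 4.04 and 4.07.

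Whether momelotinib moved the diet's changes back was asked by setting both comparisons side by side. No gene passed in either comparison in edgeR, with 1592 and 353 genes at an unadjusted p under 0.05, so the overlap of 0 was fixed and says nothing about diet genes moving back. In DESeq2 1 gene passed in both, in opposite directions (Gm14440). Of the 6 lists past the camera threshold in both comparisons, 5 went in opposite directions (interferon stimulated genes, MHC class I presentation, and T cell, neutrophil and endothelial markers) and the unfolded protein response fell in both. With an estimated correlation 0 lists passed in either comparison, and without HFD 1 and HFD 4 the MHC class I and T cell lists changed direction between HFD_MOM and HFD. These comparisons share the HFD libraries, which alone gives opposite signs. The covariance of log2 fold changes across genes, which are not independent replicates, was -0.0689 (correlation -0.388), and simulated unchanged groups gave -0.0682 ± 0.0061 (SD over 30 simulations), a difference of -0.000699. The simulated correlation was -0.452 ± 0.0299, more negative than the observed. With 1 library left out the covariance varied more than in the simulations (SD 0.0378), from -0.181 without HFD_MOM 4 and -0.115 without HFD 2 to -0.045. With the HFD libraries split between the comparisons, the covariance averaged 0.0293 over 6 splits (-0.0522 to 0.0842).

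What remained different from chow under the inhibitor was asked by comparing HFD_MOM with control. Cpt1a averaged 53.9 ± 7.04 CPM (SD, n = 4) against 29.5 ± 5.58 (n = 3), a log2 difference of 0.87 (SE 0.12), and Plin2 20.8 ± 1.33 against 12.0 ± 2.15, a difference of 0.80 (SE 0.13). Itgax differed by 0.74 (SE 0.14). Ubr4, a ubiquitin ligase, differed by -0.79 (SE 0.14), Zfp236 by -0.36 (SE 0.07) and Smg6 by -0.32 (SE 0.07). None of the 6 passed (edgeR, adjusted p = 0.233 to 0.361), and no gene of 15761 did in edgeR, while DESeq2 called 81 (51 higher, 30 lower). In edgeR 1703 genes had an unadjusted p under 0.05 (832 higher, 871 lower), where chance would give 788.1. With 1 library left out this count ran from 806 (without control 1) to 2061 (without control 3). The fatty acid oxidation and PPAR list rose: 20 of 21 were higher and 13 passed when adjusted over the list alone (camera from limma, adjusted p = 7.3e-10, and adjusted p = 0.444 with an estimated correlation). It was the 1 list past fry's threshold (limma, adjusted p = 0.0472; 6.98e-05 for change in either direction). Angptl4, a PPAR target and member of the SASP list, differed by 1.79 (SE 0.43), and Fabp4, the adipocyte marker, by 0.70 (SE 0.22).

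Interferon stimulated genes (47 of 54 higher; Parp9 0.34, SE 0.12), MHC class I (16 of 16; B2m 0.76, SE 0.18), MHC class II (8 of 8; Cd74 0.45, SE 0.26), NF-kB targets (22 of 22; Tnfaip3 0.76, SE 0.21), JAK-STAT feedback (16 of 18; Pim1 0.66, SE 0.21) and JAK-STAT components (17 of 22; Ifngr2 0.37, SE 0.13) rose against control. So did T cell (14 of 14; Cd4 1.54, SE 0.42), B and plasma cell (14 of 14; Igkc 1.01, SE 0.22), macrophage (16 of 19; Lgals3 0.73, SE 0.25), fibroblast (21 of 22; Col6a1 1.70, SE 0.44) and acinar markers (30 of 31; Try10 0.77, SE 0.51). The adjusted p of these lists in camera from limma ran from 5.49e-07 to 0.0267, and from 0.444 to 0.66 with an estimated correlation. As shares of all counts, exact permutation p was 0.40 for acinar, 0.80 for fibroblast and 0.971 for macrophage markers. It was 0.114 for T cell and 0.0571 for B and plasma cell markers. Beta identity (22 of 25 lower; Nkx6-1 -0.41, SE 0.11), secretory granule (25 of 26; Unc13a -0.51, SE 0.16), unfolded protein response (21 of 28; Ern1 -0.25, SE 0.09), heat shock (9 of 12; Hsph1 -0.54, SE 0.16), cholesterol synthesis (19 of 25; Cyp51 -0.19, SE 0.08), fatty acid synthesis (10 of 14; Acly -0.44, SE 0.16) and delta and PP cell markers (5 of 6; Sst -0.43, SE 0.17) fell. Their adjusted p in camera from limma ran from 5.21e-08 to 0.0385, and from 0.444 to 0.529 with an estimated correlation. The mean of the heat shock list was positive (0.03) while its median was -0.18. The other lists that rose were beta disallowed genes (15 of 15; Mgst1 0.91, SE 0.23), SASP (35 of 38), immediate early (22 of 22; Jund 0.38, SE 0.11), ribosomal (35 of 35; Rpl10 0.39, SE 0.13), cell cycle (34 of 40; Cdc20 0.61, SE 0.23), p53 targets (14 of 21; Trp53inp1 0.51, SE 0.10), lysosome and autophagy (15 of 20; Ctsz 0.50, SE 0.12) and mitochondrially encoded genes (13 of 13; mt-Nd6 1.05, SE 0.22). Their adjusted p in camera from limma ran from 1.42e-06 to 0.0214, and from 0.444 to 0.529 with an estimated correlation. In all 27 lists passed (20 higher, 7 lower), and 12 did with the T and B cell marker covariate, under which the interferon median was 0.091 and the MHC class II, cholesterol synthesis, ribosomal, acinar, and B and plasma cell lists turned, the last being part of the covariate. With the adipocyte marker covariate the list of interferon stimulated genes did not pass (median 0.00428, camera from limma, adjusted p = 0.68), nor did the JAK-STAT component, p53, heat shock, lysosome and autophagy, macrophage and acinar lists. Adjusted over the list alone, 5 MHC class I genes, 2 T cell and 3 B and plasma cell markers, and 1 gene each of the disallowed, p53, lysosome and mitochondrially encoded lists passed as higher. Lower were 3 heat shock genes and 1 gene each of the JAK-STAT feedback and component lists, and apart from the fatty acid oxidation list 0 genes passed in the other lists named here. In lists that did not pass, 1 hypoxia gene was lower and 1 NRF2 gene higher past 0.05 over the list alone. Ins1, Ins2 and Gcg differed by -0.27 (SE 0.29), -0.29 (SE 0.35) and -0.41 (SE 0.31), Jak1 by 0.06 (SE 0.08), Jak2 by 0.25 (SE 0.09), Stat3 by -0.07 (SE 0.11), Socs3 by 0.46 (SE 0.18), Cish by 1.33 (SE 0.999) and Cdkn1a by 0.30 (SE 0.28). Without HFD_MOM 4, where Cish stood at 40.4 CPM, Cish differed by 0.33 and Cdkn1a by -0.06, and with the acinar covariate Cish differed by 0.12.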

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

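Among the tests below, the splits that count genes past the threshold were chosen after the result was seen. Of 190 sets of 4 libraries examined, 14 held a library far from the other 3, where chance gives about 1 in 20 (9.5). In HFD 1, Cish, a feedback target of STAT5, stood at 35.2 CPM where the others lay between 4.93 and 6.96. Over all libraries Cish was highest in HFD_MOM 4 (40.4 CPM) and HFD 1, the libraries with intestinal transcripts. Whether its high values come with that tissue was not tested. In HFD 2, Jak2 was lowest at 21.01 CPM (others 26.5 to 26.9) and delta and PP cell markers highest at 0.351% of counts (0.266% to 0.278%). In HFD 3, Col6a1 (10.5 CPM), Lgals3 (26.9 CPM) and Rab33b (19.1 CPM) were highest, against at most 6.46, 15.9 and 18.4. In HFD 4, Klf2 was highest at 27.2 CPM (16.7 to 18.0) and Cyp51 lowest at 20.5 (22.9 to 23.4). In HFD_MOM 1, Angptl4 (4.69 CPM) and Ltf (0.529 CPM) were highest, against at most 1.94 and 0.126. In HFD_MOM 2, Socs3 was highest at 8.99 CPM (8.04 to 8.07) and Ubr4 lowest at 150.5 (177.9 to 181.9). In HFD_MOM 4, Cdkn1a was highest at 26.2 CPM (10.9 to 12.8) and Plaur lowest at 2.45 (2.85 to 2.94).

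Counts of 0 called genes are met by all 35 splits in each comparison and say nothing about chance. Between HFD and control 0 genes passed in edgeR (1592 at an unadjusted p under 0.05, 73 in DESeq2). The highest other count was 87, from a split that set HFD 1, HFD 3 and HFD 4 against HFD 2 and the controls, and another that placed HFD 2 with controls 1 and 2 gave 36. Splits that call this many genes point to a structure of the samples that the groups do not describe. In the split of 36, HFD 2 and controls 1 and 2 had lower acinar marker shares (21.8%, 24.5% and 27.4%) than the rest (29.15% to 40.14%). Their shares of Ins1 and Ins2 were higher (13.4%, 12.9% and 11.3% against 6.05% to 9.1%). The split of 87 did not follow acinar content, as control 3 (38.8%) stood with HFD 2. Whether acinar content gives these calls was not tested. At an unadjusted p under 0.05, 6 of the 35 splits gave as many as 1592 (highest 3305). For lists, 2 of 35 gave as many as the 24 (highest other 24, median of the others 15.5). Chance was not excluded for either count. Between HFD_MOM and HFD, 0 genes passed in edgeR (353 at an unadjusted p under 0.05, 2 in DESeq2, highest other split 1). Of the 35 splits, 29 gave as many as the 353 (highest 2627) and 26 as many as the 13 lists (highest 22, median of the others 14). Between HFD_MOM and control 0 genes passed in edgeR (1703 at an unadjusted p under 0.05, 81 in DESeq2, highest other split 0). Here 4 splits gave as many as the 1703 (highest 2360) and 2 as many as the 27 lists (highest other 27, median of the others 15). Chance was not excluded for these counts at an unadjusted p or for these counts of lists.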

How the results depend on the processing

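The tests with a T and B cell or an adipocyte covariate and without pairs of libraries were chosen after seeing the data. Counts of called genes were 0 to 2 in every setting but DESeq2. Between HFD and control, 0 genes became 73 in DESeq2, 2 without a filter, 2 with voom quality weights, 1 with the acinar covariate, 2 at a threshold of 0.10, and 2 without the libraries with intestinal transcripts. Leaving out 1 library gave 0 to 2, the 2 without HFD 1. Between HFD_MOM and HFD, DESeq2 gave 2 and leaving out 1 library 0. Between HFD_MOM and control, DESeq2 gave 81, no filter 1, and leaving out 1 library 0 to 1, the 1 without control 2. The cause was not tested. Genes moved back numbered 0, a count fixed by the 0 genes called, and 1 in DESeq2. Among 24, 13 and 27 lists in the same order, 0 passed with an estimated correlation in each, fry passed 0, 0 and 1, and leaving out 1 library gave 20 to 26, 8 (without HFD_MOM 4) to 18 (without HFD 2) and 21 to 28. Of these 8 and 18 lists, 5 and 10 were among the 13 in the same direction. The adipocyte covariate gave 22, 13 and 23, and turned endothelial markers on the diet (median -0.00839). The T and B cell covariate gave 10 and 12 lists against control. Between HFD_MOM and HFD it gave 7 higher and 8 lower, more than the 13 lists without it. With this covariate and an estimated correlation 0 passed in each comparison. Without the libraries with intestinal transcripts 6 passed between HFD_MOM and HFD.

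With the T and B cell covariate these lists turned on the diet, given by their medians: beta identity 0.086, beta disallowed -0.117, secretory granule 0.0403, MHC class II -0.0525, cell cycle 0.0129 (camera pointing down), ribosomal proteins -0.14, fibroblast -0.17, and B and plasma cell markers -0.29, which are part of the covariate, so that their turn says nothing. Between HFD_MOM and control MHC class II was -0.0169, cholesterol synthesis 0.0131, ribosomal proteins -0.0203, B and plasma cell markers -0.25 and acinar markers 0.13 (camera pointing down). Without the libraries with lymph node transcripts, medians between HFD_MOM and HFD were 0.0174 for MHC class I, 0.12 for T cell and 0.0392 for erythrocyte markers, and ATF4 ran from 0.0263 without HFD_MOM 4 (camera pointing down) to 0.352. The cause was not tested. The covariance of -0.0689 became 0.0293 with split HFD libraries, which removes the shared libraries, and ran from -0.181 (without HFD_MOM 4; -0.115 without HFD 2) to -0.045 with 1 library left out. Single genes gave 2472 values on the same side of the threshold, 39 newly past it and 3 that moved: Cish to -0.17 on the diet without HFD 1 and to -0.69 between HFD_MOM and HFD without HFD_MOM 4, and Cdkn1a to -0.06 against control without HFD_MOM 4. Marker shares passed 0 tests in each setting, which this design could not exceed. No paired analysis was possible because replicate numbers only name libraries. At these depths Cdkn2a, with 2 to 8 counts, was too low to test.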

Other observations

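Apart from the 2 tests of transcript length and the one with the adipocyte covariate, the tests in this part were chosen after the result was seen. The adipocyte covariate was itself chosen after seeing the data, though before its own result was seen. The demand that a value differ by more than its spread before it counts against an explanation was also made after the result was seen. Of the genes DESeq2 called against control, 13 of 73 in HFD and 15 of 81 in HFD_MOM were immunoglobulin genes, all higher, and 26 genes were called in both comparisons. Immunoglobulin genes took 0.356% ± 0.0573 (SD, n = 3) of counts in control, 0.768% ± 0.219 (n = 4) in HFD and 0.729% ± 0.149 (n = 4) in HFD_MOM. Transcripts of intestine and of lymph node stroma varied between libraries of the same group. The intestinal apolipoprotein gene Apoa4 stood at 446 CPM in HFD 1 and 642 in HFD_MOM 4 and at no more than 35.7 in the other libraries, and the first principal component (36.0% of variance) set these 2 libraries apart. Ccl21a, a chemokine of lymph node stroma, stood at 95.3 CPM in HFD 1 and 51.5 in HFD 4 and at no more than 4.55 elsewhere, and Glycam1, of lymph node vessels, at 53.6 and 30.1 against no more than 1.87. Madcam1 followed them (4.76 and 7.83 CPM, no more than 1.004 elsewhere), and Ccl19 in part, at 5.85 in HFD 1 and 3.78 in HFD 4 but 4.00 in HFD_MOM 2. Cxcl13 did not, at 2.81 CPM in HFD 1, 20.2 in HFD 4 and 21.03 in HFD 3. These genes were chosen after their values were seen.

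Interferon stimulated genes were higher on the diet and lower with momelotinib than without, and with the T and B cell marker covariate the median log2 difference went from 0.50 to 0.22 on the diet (jackknife SE 0.21) and from -0.19 to -0.15 with momelotinib (jackknife SE 0.14), and without the libraries with lymph node transcripts the latter was -0.11. The list passed camera from limma at the preset correlation under each (adjusted p = 1.22e-05, 0.0021 and 0.000172), but with the covariate and an estimated correlation it did not (adjusted p = 0.895 and 0.843). The medians left lay within their spread of the bound set for these explanations, so the part that lymphoid cells or lymph node tissue may play cannot be told apart from a response within islet cells. Inhibition of JAK1/2 would also lower the JAK-STAT feedback list, whose median was -0.14 without passing (camera from limma, adjusted p = 0.161), which leaves it open. Of the 35 splits, 3 gave a median as far from 0 on the diet (highest other 0.57) and 8 with momelotinib (0.31). Chance was not excluded there. Between HFD_MOM and control 1 of 35 did, the real one (0.29, highest other 0.24), which is the smallest share that 35 splits can give. The list was picked from many after its result was seen, so chance was not excluded there either. With the T and B cell or adipocyte covariate this last median was smaller.

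Fatty acid oxidation and PPAR targets were higher in both diet groups. The median on the diet was 0.32 (jackknife SE 0.126). It was 0.25 without the libraries with intestinal transcripts, 0.30 with the acinar covariate and 0.38 with the T and B cell covariate. These values argue against the intestinal tissue of HFD 1 and HFD_MOM 4, acinar content or lymphoid cells as the whole cause. Intestinal transcripts in other libraries were not removed, with Apoa4 at 35.7 CPM in HFD 2, 15.7 in HFD 3 and 22.5 in control 2. Chance was not excluded on the diet, where 3 of 35 splits gave a median as far from 0 (highest other 0.34). Between HFD_MOM and control 1 of 35 did so, the real one, by a small margin (0.3602, highest other 0.3601). This test too was chosen after the result was seen, and 1 of 35 is the smallest possible share. Chance was not excluded there either. With the adipocyte markers as a covariate the median was 0.23, within its spread of the bound. Most counts of that covariate were Fabp4 (up to 368 in a library), while Adipoq and Plin1 had at most 4 and Lep 1. It is therefore a poor measure of adipose tissue. The test cannot decide between adipose tissue and a response of islet cells to dietary fat. That response is one hypothesis these values leave open, and the unrecorded age of the mice is a cause not tested.

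Long transcripts were common among the genes lower than in control. Genes with an unadjusted p under 0.05 had a median transcript length of 4402 bases when lower with momelotinib and 2699 when higher, against 3026 for all genes. Across genes, which are not independent replicates, log2 difference fell with length (Spearman rho -0.18), but 9 of 35 splits gave a rho as far from 0 (highest other 0.23), so length-dependent recovery of transcripts may contribute and cannot be told apart from other differences between libraries. With the acinar covariate rho was -0.10, within the spread of the splits (SD 0.14), which leaves acinar content open too.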
